A study of Mus musculus with 8 samples.

How the data were processed

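RNA of sorted mouse intestinal epithelial cells was sequenced in 8 libraries. Per the labels' protocols, the cells came from 6-week-old male littermates that carried either Sox4 alleles flanked by loxP sites alone (control) or the same alleles with villin-Cre, which deletes Sox4 in the intestinal epithelium (Sox4cKO). From each animal, CD326-positive epithelial cells were sorted by flow cytometry into a CD44-negative gate that enriches for villus cells (CD44minus) and a CD44-positive gate that enriches for crypt cells (CD44plus), with 50000 cells per library. Each of the 4 groups of genotype and gate has 2 libraries. The replicate numbers mark animals within a genotype. The animal number in the names of the deposited tables is the same for both gates, so the CD44minus and CD44plus libraries of 1 replicate number and genotype come from 1 animal, whereas a control and a Sox4cKO library of the same number share only the number. The deviations of the libraries from their group means, correlated across genes between gates, gave 0.103 for control and 0.526 for Sox4cKO.

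The deposited tables hold raw read counts per gene symbol, one table per library, with the summary lines that HTSeq writes after the genes. Per the labels' protocols, libraries were made from total RNA with a strand-marking kit for picogram input. The submitters' processing notes name bcl2fastq 2.17.4, Trimmomatic 0.36, STAR 2.2.5b, HTSeq 0.6.1p1 and the mm10 build, without their settings. The strand setting of the counting is not given there, so genes that overlap another gene on either strand are uncertain. Reads placed at more than 1 site were not counted to genes, so members of near-identical families (Mcpt, Defa, Saa, histone and ribosomal protein genes) are uncertain too. The tables hold 23366 gene symbols, of which 21732 were matched to the GENCODE annotation of GRCm38 by symbol, 1274 by a single RefSeq synonym and 360 not at all (98.5% matched). No symbol of a mitochondrially encoded gene is in the tables, so that list could not be examined.

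Depth differed widely, and levels are given as CPM, reads of a gene scaled to one common library total. Gene counts per library were 886194 and 2327002 in control CD44minus, 1175251 and 6963345 in Sox4cKO CD44minus, 12249272 and 6007554 in control CD44plus and 7679575 and 13238050 in Sox4cKO CD44plus, in the order replicate 1 and replicate 2, which holds for all value pairs below. Of the uniquely placed reads, 96.3 and 92%, 96.6 and 76.8%, 77.8 and 74.5% and 79.3 and 64.6%, in the same order of groups, were counted by HTSeq to no gene. Where these reads lie is not given, so they may include reads in introns or on a strand that was not counted. A count of 0 allows up to 3 counts, which is 3.39 CPM of gene counts in control CD44minus replicate 1 and 0.227 CPM in Sox4cKO CD44plus replicate 2. Intervals and this floor cover counting error only, because the reads carry no molecular identifiers. The 45S ribosomal RNA gene Rn45s took 7.95% to 12.7% of gene counts.

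Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The main analysis fitted the 4 groups in all 8 libraries with edgeR's quasi-likelihood test, after edgeR's filterByExpr with a minimum count of 10 and scaling by trimmed mean of M values (TMM), and Benjamini-Hochberg adjustment over the 20427 genes tested. The threshold was an adjusted p of 0.05. CPM values below are scaled by the TMM factors, which were 1.68 and 1.09 in control CD44minus, 1.72 and 0.527 in Sox4cKO CD44minus, 0.914 and 0.912 in control CD44plus and 0.901 and 0.797 in Sox4cKO CD44plus. Fold changes carry the standard error (SE) of the fit. There were 5 comparisons: Sox4cKO against control in each gate, CD44plus against CD44minus in each genotype, and the difference of the genotype effect between gates. The biological coefficient of variation was 0.616 in this fit, 0.335 with the CD44plus libraries alone and 0.76 with the CD44minus libraries alone. Counts of replicates differed by 7.86, 61.6, 9.26 and 31 times the Poisson variance in control CD44minus, Sox4cKO CD44minus, control CD44plus and Sox4cKO CD44plus, and their log CPM correlated across genes at 0.887, 0.763, 0.964 and 0.961. The first principal component of log CPM held 68.1% of the variance and set 3 CD44minus libraries apart, while Sox4cKO CD44minus replicate 2 lay among the CD44plus libraries. The second held 17.3% and set that library apart.

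Before the data were examined, 23 gene lists and 3 lists defined by symbol pattern were fixed, together with the comparisons, most of the alternative settings and the rule for naming genes. The lists cover cell types of the epithelium (enteroendocrine, tuft, goblet, Paneth, stem cell and enterocyte), secretory progenitor and Notch genes, Wnt targets, cell cycle, and SoxC and Sox9. They cover other cells a sort can hold (T cell and intraepithelial lymphocyte, B, plasma and myeloid cell, stroma and endothelium, red blood cell). The rest are dissociation stress, interferon response, class II antigen presentation, epithelial antimicrobial genes, cholesterol synthesis, unfolded protein response, nuclear-encoded oxidative phosphorylation, proximal and distal gut, and by pattern ribosomal protein, histone and mitochondrially encoded genes. A set test was made for the 24 lists with at least 3 genes tested, by limma's camera with a preset correlation of 0.01 between genes, again with an estimated correlation, and by limma's fry, each adjusted over the lists of a comparison. For members of a list, p was also adjusted over the list alone. Named genes are, per comparison, up to 10 genes per direction with the greatest fold changes among those that passed, had at least 2 CPM and did not overlap between groups, filled to 5 by unadjusted p, and up to 4 genes per list. For the difference of the genotype effect they are up to 5 genes per direction. The text names part of these, and genes of the Sox, stem cell, tuft cell and enteroendocrine lists may appear in any comparison.

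Settings chosen beforehand as alternatives were a threshold of 0.1, DESeq2 size factors, upper quartile factors, and no filter or a stricter one (1 CPM in 2 libraries and 50 counts). Also chosen beforehand were a fit of the 4 libraries compared, a replicate block, removal of the 20 highest genes, DESeq2, limma-voom with the animal as a random block, and leaving out each library. Alternatives chosen after seeing the data were total-count scaling, subtraction of background, limma-voom with sample quality weights, leaving out each library in the 4-library CD44plus fit, and the set tests in that fit. The count of enteroendocrine genes adjusted over the list alone was also made a result after seeing the data. Where leaving out a library leaves 1 library in a group, that library is assumed to vary like the other groups. Groups of 2 allow neither a test for outlying libraries nor a count of other splits of the samples.

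Background was measured as reads on 1416 olfactory and vomeronasal receptor genes, which the gut epithelium is not known to express. The level of background per kilobase of exon was taken from these genes, scaled by 4.32 to the level of genes with at most 1 count in the library of lowest background, and subtracted from each gene. Bootstrap intervals used 2000 resamples of genes. The code was tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold among those of at least 1 CPM, at the depths and spread estimated for each fit. In the comparison of genotypes in CD44plus, edgeR recovered 0 of the 2-fold and 1 of the 4-fold genes with all 8 libraries (1 call, 0 false), and 21 and 65 with the 4 CD44plus libraries (97 calls, 7 false). In CD44minus it recovered 0 of either with all 8 libraries. With a coefficient of variation of 0.1 it recovered 72 and 91 in CD44plus with all 8 libraries. With all 8 libraries DESeq2 made 30 calls between control gates, of which 14 were false, and 32 between Sox4cKO gates, of which 16 were false. With the 4 Sox4cKO libraries it made 72 calls between gates, of which 56 were false. A simulated background of 3 reads per kilobase, added alike to all annotated genes, was read back as 2.995 from the receptor genes before scaling. This tested neither the scaling by 4.32 nor the subtraction. A first version of the simulation recovered no gene with the 4 CD44plus libraries. It drew changed genes from all those tested and gave each fit the spread of the 8-library fit, and it was replaced by this version after its outcome had been seen. Sequences outside the deposited tables were not analysed here.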

Results

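Sox4 encodes a transcription factor of the SoxC group and was the gene deleted in this series. It was read at 1438 and 658 reads (128 and 120.2 CPM) in control CD44plus and at 123 and 271 reads (17.8 and 25.7 CPM) in Sox4cKO CD44plus. In the CD44minus gate it gave 10 and 21 reads (6.74 and 8.26 CPM) in control and 4 and 1 reads (1.98 and 0.272 CPM) in Sox4cKO. Exact Poisson 95% intervals were 4.79 to 18.4 and 13 to 32.1 reads in control and 1.09 to 10.2 and 0.0253 to 5.57 reads in Sox4cKO. Sox4 was 5.71-fold lower in Sox4cKO than in control in CD44plus (log2 fold change -2.51, SE 0.61) and 7.75-fold lower in CD44minus (-2.95, SE 0.83). The background measure below would put 12.3 and 12.1 reads on Sox4 in control CD44minus and 18.5 and 4.95 in Sox4cKO CD44minus. Apart from control replicate 2, Sox4 was thus not above this predicted level in that gate. In Sox4cKO replicate 1 the 4 reads, with an interval up to 10.2, lay under the 18.5 predicted. The measure thus overstates the background on Sox4 in that library. It cannot tell whether Sox4 lay above background in control replicate 1. The fold in CD44minus rests on few reads and is uncertain. Neither decrease passed edgeR's test over all genes. Among the 8 genes of the SoxC and Sox9 list, adjusted over the list alone, both passed (edgeR adjusted p = 0.00513 in CD44plus and 0.018 in CD44minus). In the fit of the 4 CD44plus libraries the decrease passed over all genes (-2.51, SE 0.22, edgeR adjusted p = 0.0186). Sox4 was higher in CD44plus than in CD44minus in control (edgeR adjusted p = 0.014) and in Sox4cKO (edgeR adjusted p = 0.0139). The folds of 16.4 and 22.3 are over the CD44minus counts and as uncertain as these. The gene has 1 annotated exon of 4795 bp on GRCm38 (mm10) chromosome 13, 28948919 to 28953713.

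**Figure D1:**
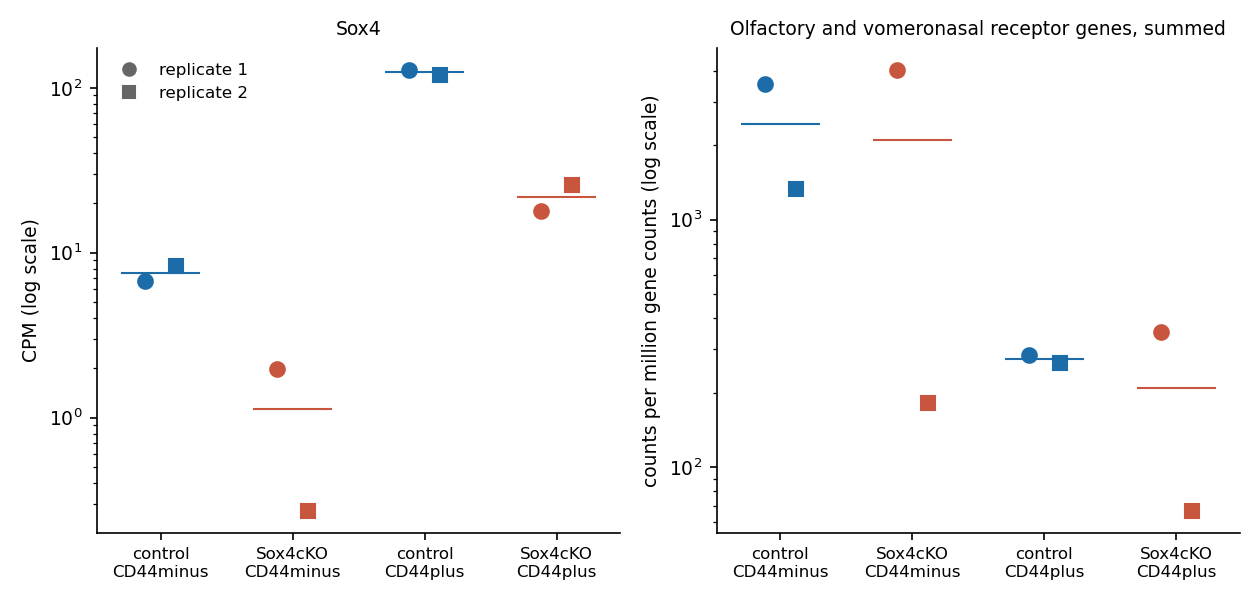
The first panel plots Sox4 in CPM and the second the olfactory and vomeronasal receptor genes in CPM of gene counts, for each of the 8 libraries, with log axes. Sox4 lay at 128 and 120.2 CPM in control CD44plus and at 17.8 and 25.7 CPM in Sox4cKO CD44plus, and receptor genes took 4029.8 CPM in Sox4cKO CD44minus replicate 1 against 66.8 CPM in Sox4cKO CD44plus replicate 2.

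Receptor genes of smell and of pheromones, which gut epithelium is not known to express, served as a measure of background. In CPM of gene counts, without TMM factors, they took 3547 and 1336 CPM in control CD44minus and 4029.8 and 182 CPM in Sox4cKO CD44minus. This was against 283 and 264 CPM in control CD44plus and 351 and 66.8 CPM in Sox4cKO CD44plus. Background on this scale made up 24.5 and 9.39% and 27.7 and 1.22% of the gene counts in the CD44minus libraries of control and Sox4cKO, and 0.469% to 2.54% in CD44plus. The Sox4cKO CD44minus replicates therefore stand far apart in this measure, and every result that uses the CD44minus gate rests on libraries of unequal background.

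In the crypt-enriched CD44plus gate, most genes of enteroendocrine cells, the hormone-secreting cells of the gut epithelium, were lower in Sox4cKO than in control. Cpe, which trims prohormones to their active form, was at 67 and 81.1 CPM in control and 8.68 and 10.4 CPM in Sox4cKO, 7.73-fold lower. Gip, the incretin hormone of K cells, was at 1212 and 2197 CPM in control and 183 and 255 CPM in Sox4cKO (7.78-fold lower). The granule protein gene Chga lay at 633 and 566 CPM in control and 132 and 168 CPM in Sox4cKO and Chgb at 2503 and 2669 CPM in control and 789 and 1049 CPM in Sox4cKO. The transcription factor genes Pax6 (31.1 and 40.5 against 5.64 and 7.11 CPM) and Rfx6 (59.2 and 83.5 against 16.8 and 16.7 CPM), which act in enteroendocrine and pancreatic islet cells, were lower by 5.59-fold and 4.26-fold.

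Several other hormone genes were lower in both Sox4cKO libraries than in both control libraries. Cholecystokinin (Cck) was at 75.3 and 67.4 CPM in control and 21.8 and 27.4 CPM in Sox4cKO, and somatostatin (Sst) at 118 and 247 against 42.5 and 58.3 CPM. Secretin (Sct) was at 67.7 and 84.7 against 27.6 and 36 CPM and proglucagon (Gcg) at 67.6 and 65 against 23.4 and 28.8 CPM. Peptide YY (Pyy) was at 14.3 and 9.13 against 4.34 and 5.68 CPM. Tac1, the substance P precursor of enterochromaffin cells, was at 42 and 41.6 against 9.54 and 9 CPM. Neurog3, the transcription factor that starts the enteroendocrine lineage, was at 11.8 and 11.1 CPM in control and 9.4 and 12.5 CPM in Sox4cKO (log2 fold change -0.065, SE 1.07), a difference within its error and of either sign across alternatives. Tph1, the first enzyme of serotonin synthesis in the gut and also read in mast cells, was at 77.3 and 76.2 CPM in control against 36.4 and 142 CPM, with a log2 fold change of 0.22 that was -1.07 without Sox4cKO CD44plus replicate 2. Ghrelin (Ghrl) was at 45.2 and 61.4 against 27.8 and 51.4 CPM.

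Of the 33 enteroendocrine genes tested, 31 had a negative log2 fold change, with a median of -1.65. The list as a whole was lower by limma's camera (adjusted p = 1.41e-51, adjusted p = 0.0791 with an estimated correlation, where the unadjusted p is 0.0033), and limma's fry gave an adjusted p of 0.169. Adjusted over the list alone, 8 of its genes were lower in edgeR's test, among them Cpe (-2.95, SE 0.61, adjusted p = 0.0044), Pax6 (-2.48, SE 0.71, adjusted p = 0.0271) and the granin-related Scg3 (-2.19, SE 0.76, adjusted p = 0.0437). Over all genes edgeR called 0 genes in this comparison. At an unadjusted p under 0.05 there were 128 (37 higher, 91 lower), and DESeq2 and limma-voom with the animal as a random block also called 0. Without any effect, a share of 0.05 of the 20427 genes tested would be expected at that p. The 128 are fewer, so edgeR's test was conservative here and their count is no sign of an effect. The fit of the 4 CD44plus libraries called 17 genes, all lower, with edgeR adjusted p from 0.0186 for Sox4 to 0.0494, of which 11 are enteroendocrine genes. In that fit 31 of 32 enteroendocrine genes tested were negative (median -1.70), 28 were lower when adjusted over the list alone, and limma's camera gave an adjusted p of 1.20e-117 (adjusted p = 0.162 with an estimated correlation). With all 8 libraries the count of 8 genes was 27 without Sox4cKO CD44minus replicate 1 and 27 without its replicate 2, 1 without control CD44plus replicate 1, and 0 without control CD44plus replicate 2 or either Sox4cKO CD44plus library. The count over all genes was 24 (4 higher, 20 lower) without Sox4cKO CD44minus replicate 1 and 4 without its replicate 2, and in the 4-library fit 58 (5 higher, 53 lower) and 216 (165 higher, 51 lower) without control replicate 1 and replicate 2. Without Sox4cKO replicate 1 and replicate 2 that fit called 1554 (977 higher, 577 lower) and 200 (58 higher, 142 lower), so the genes called were not all lower in any of these 4 and were mostly higher in 2.

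**Figure D2:**
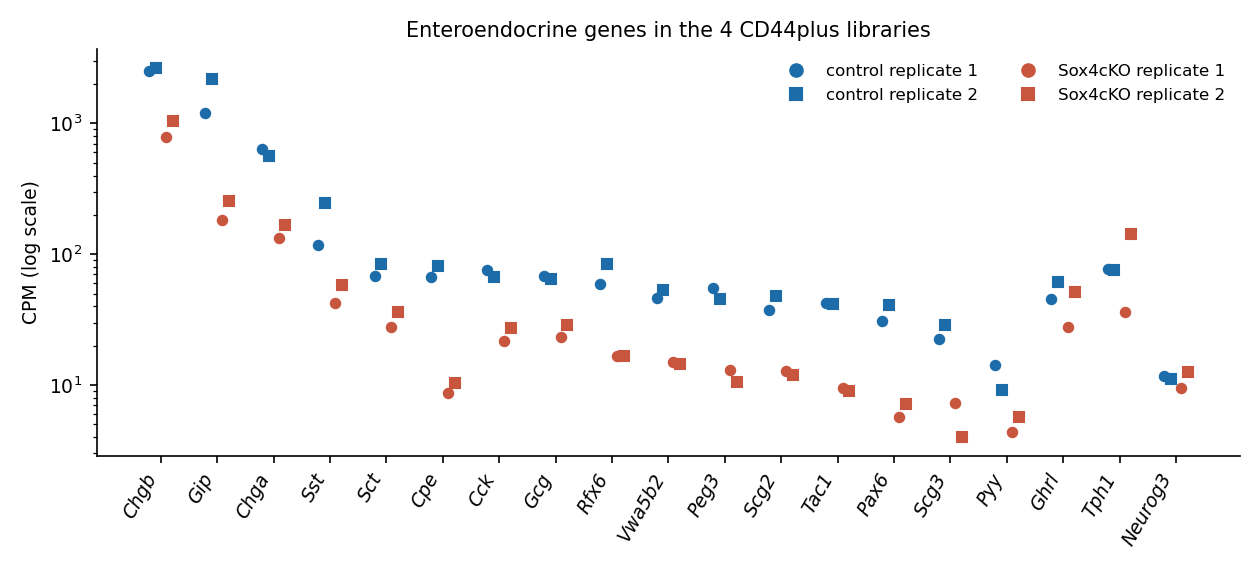
Enteroendocrine genes in the 4 CD44plus libraries, each point the CPM of 1 library on a log axis, control and Sox4cKO in separate colours. Gip lay at 1212 and 2197 CPM in control and 183 and 255 CPM in Sox4cKO, and Neurog3 at 11.8 and 11.1 and 9.4 and 12.5 CPM.

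Intestinal stem cell genes were slightly lower in Sox4cKO CD44plus. Lgr5, the R-spondin receptor that marks crypt base columnar stem cells, was at 91.2 and 99.7 CPM in control and 41.1 and 47.8 CPM in Sox4cKO (-1.10, SE 0.63), and Slc14a1, a urea transporter gene of that list, at 56.1 and 59.9 against 20 and 24.2 CPM (-1.39, SE 0.62). Olfm4, a secreted protein abundant in crypt base cells, differed little (4340 and 4882 against 3767 and 3552 CPM), as did the stem cell transcription factor gene Ascl2 (21.3 and 23.9 against 17.2 and 19.6 CPM) and Smoc2 (285 and 251 against 207 and 195 CPM). Of 22 genes 20 were negative, with a median of -0.34 (limma's camera adjusted p = 0.00485, adjusted p = 0.453 with an estimated correlation, limma's fry adjusted p = 0.00433). Adjusted over the list alone, 0 stem cell genes passed in edgeR with all 8 libraries, and Lgr5 and Slc14a1 passed with the 4 CD44plus libraries (edgeR adjusted p = 0.00612 and 0.00301). The camera call of the list was lost without control CD44plus replicate 2 (median -0.31, adjusted p = 0.063) and without Sox4cKO CD44plus replicate 1 (-0.48, adjusted p = 0.27). The SoxC and Sox9 list, which holds Sox4 itself, had a median of -0.24 (6 of 8 negative, limma's camera adjusted p = 0.0221, adjusted p = 0.453 with an estimated correlation), with Sox9 at 419 and 413 against 330.2 and 338 CPM. That call was lost without control CD44plus replicate 1 (median -0.061), Sox4cKO CD44plus replicate 1 (-0.93) or Sox4cKO CD44plus replicate 2 (-0.14).

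Other epithelial programs differed little between genotypes in CD44plus. Median log2 fold changes, each with its adjusted p by limma's camera, were -0.033 for 20 goblet cell genes (0.726), -0.094 for 18 Paneth cell genes (0.961) and 0.14 for 35 enterocyte genes (0.198). They were 0.081 for 21 secretory progenitor and Notch genes (0.255), -0.12 for 20 Wnt targets (0.446) and 0.013 for 33 cell cycle genes (0.506). None of these passed by camera. Nor did nuclear-encoded oxidative phosphorylation genes (0.018, 0.734), ribosomal protein genes (-0.055, 0.945), or histone genes (-0.15, 0.161). The same held for dissociation stress genes (0.16, 0.24), stroma and endothelium genes (-0.18, 0.625) and genes of the proximal small intestine (-0.35, 0.392). Of the last, Pdx1, a duodenal transcription factor gene, was at 15.6 and 9.13 against 6.07 and 6.06 CPM and Onecut2 at 208 and 120.4 against 89.2 and 106 CPM. The signs of the cell cycle, Notch and oxidative phosphorylation medians turned under other scalings. The red blood cell list had 2 genes tested and no set test (median 1.22).

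Genes of lymphocytes and other immune cells were higher in Sox4cKO CD44plus, mainly in replicate 2. Itgae, the integrin chain that holds intraepithelial lymphocytes to E-cadherin, was at 277 and 396 CPM in control and 339 and 1044 CPM in Sox4cKO, and the activation marker Cd69 at 74.7 and 138 against 102 and 345 CPM. The median level of the T cell list was 76.3 and 140.1 CPM in control and 92.9 and 272 CPM in Sox4cKO. All 18 T cell genes tested had a positive log2 fold change (median 0.55, limma's camera adjusted p = 2.52e-05, adjusted p = 0.528 with an estimated correlation). So had all 16 B, plasma and myeloid cell genes (0.75, camera adjusted p = 8.79e-07, adjusted p = 0.453 with an estimated correlation). Among the latter, the signalling adaptor Tyrobp was at 17.3 and 32.7 against 25.5 and 85.4 CPM, Fcer1g at 16.6 and 41.6 against 36.7 and 106 CPM and the integrin gene Itgax at 89.2 and 127 against 116 and 374 CPM. The T cell median was -0.21 without Sox4cKO CD44plus replicate 2 and 0.23 without control CD44plus replicate 1, and neither call held. The B, plasma and myeloid median was 0.24 and 0.28 without these libraries, again without a call.

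Tuft cells, the chemosensory cells of the epithelium, gave genes of both signs. Alox5ap (16.6 and 31.4 against 28.8 and 120.4 CPM) and Alox5 (13 and 25.2 against 24 and 107 CPM), which make leukotrienes and are also read in leukocytes, were higher in Sox4cKO replicate 2. The tuft markers Dclk1 (29.9 and 43.3 against 24.4 and 16.5 CPM), Pou2f3 (9.47 and 15.9 against 11.7 and 7.67 CPM) and Trpm5 (33.9 and 32 against 40.2 and 35.4 CPM) were not highest there, and Dclk1 and Pou2f3 were at their lowest. Of 27 tuft cell genes 19 were positive (median 0.15, limma's camera adjusted p = 0.00485, adjusted p = 0.708 with an estimated correlation), and 7 of the 27 were at more than 2 times the highest other CD44plus library in Sox4cKO CD44plus replicate 2. The camera call was lost without that library (median 0.025) and without control CD44plus replicate 1 (0.19), and after subtraction of background (0.18, adjusted p = 0.0536).

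Of 7 mast cell protease genes, 4 were highest in Sox4cKO CD44plus replicate 2 of all libraries. Mcpt1, a protease of mucosal mast cells, was at 1094 and 1889 CPM in control CD44plus, 2218 CPM in Sox4cKO CD44plus replicate 1 and 10910 CPM in replicate 2, against 2.69 to 4.46 CPM in the CD44minus libraries. Mcpt2 was at 473, 797, 1025 and 5243 CPM in the same CD44plus libraries, and Cma2, a chymase gene, at 24.2 and 25.8 CPM in control and 47.7 and 212 CPM in Sox4cKO. The fourth was Mcpt4 (6.97, 8.22, 10.3 and 60.4 CPM). Cma1 (31 reads, 2.94 CPM there) was higher in 2 CD44minus libraries (4.04 and 4.46 CPM). These rest on 6 and 9 reads in the 2 libraries with the most background, and among the CD44plus libraries Cma1 was highest in Sox4cKO replicate 2. Tpsb2 (0.0948 CPM in that library) and Tpsab1 (0 reads in it) were higher in other libraries. These genes, apart from the Tps genes, belong to a cluster of close paralogs and their separate counts are uncertain. Outside the cluster, the mast cell carboxypeptidase Cpa3 was at 47.5, 93, 94 and 408 CPM and the IgE receptor chain Ms4a2 at 32.1, 40, 52.6 and 227 CPM. None of these differences between genotypes passed edgeR's test over all genes. Emilin2 (15.2 and 12.4 against 29.9 and 109 CPM) and Gp1ba (10.7 and 14.2 against 20.8 and 80.3 CPM), among the genes of smallest unadjusted p, were also high in that library.

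**Figure D3:**
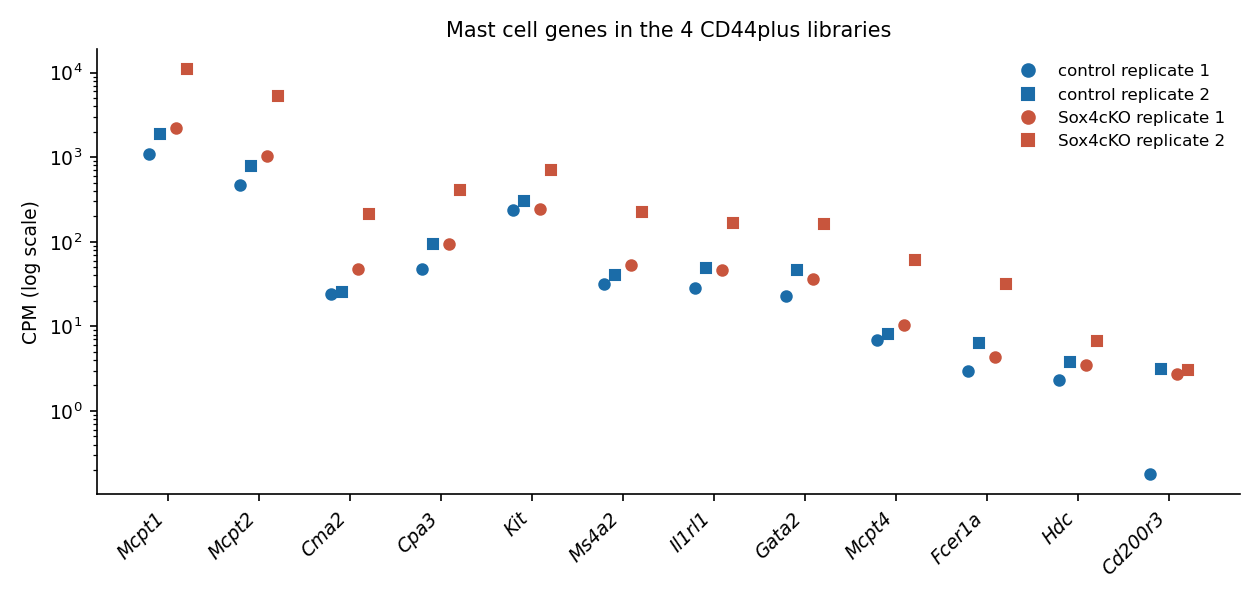
Mast cell genes in the 4 CD44plus libraries, each point the CPM of 1 library on a log axis. Sox4cKO replicate 2 held the highest value for Mcpt1 (10910 CPM), Mcpt2 (5243 CPM) and Cpa3 (408 CPM).

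Genes of further lists were higher in Sox4cKO CD44plus, none of them past edgeR's test over all genes. Duox2, the epithelial NADPH oxidase, was at 92.6 and 139 CPM in control and 309 and 174 CPM in Sox4cKO, and its maturation factor Duoxa2 at 9.74 and 13.9 against 36.6 and 21 CPM. The class II antigen genes H2-Ab1 (73.5 and 121 against 130.2 and 229 CPM) and H2-Eb1 (57.5 and 102 against 103 and 195 CPM) were higher. Class II genes are also read in B and myeloid cells, whose genes were highest in the same library, Sox4cKO replicate 2. Also higher were the interferon-induced Ifit1 (4.91 and 5.11 against 11.3 and 9.29 CPM), the endoplasmic reticulum stress gene Creld2 (45.7 and 44 against 63.8 and 60.4 CPM) and B3galt5, a glycosyltransferase of the distal gut list (11.3 and 14.1 against 38.6 and 38.3 CPM).

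As lists, epithelial antimicrobial genes were called (8 of 12 positive, median 0.76, limma's camera adjusted p = 3.33e-05, adjusted p = 0.453 with an estimated correlation). Class II antigen presentation genes (9 of 9, median 0.76, limma's camera adjusted p = 2.64e-05, adjusted p = 0.453 with an estimated correlation) were called, and so were interferon response genes (17 of 23, median 0.37, limma's camera adjusted p = 0.00145, adjusted p = 0.7 with an estimated correlation). The same holds for cholesterol synthesis genes (17 of 18, median 0.30, limma's camera adjusted p = 0.00135, adjusted p = 0.708 with an estimated correlation). Unfolded protein response genes (17 of 18, median 0.27, limma's camera adjusted p = 0.0208, adjusted p = 0.822 with an estimated correlation) and genes of the distal small intestine and colon (9 of 10, median 0.53, limma's camera adjusted p = 0.00038, adjusted p = 0.453 with an estimated correlation) were called as well. In all, 12 of 24 lists were called by camera, 0 with an estimated correlation and 1 (stem cell) by fry. Without control CD44plus replicate 1 the interferon (0.32), class II (0.37), cholesterol (0.34) and unfolded protein (0.21) calls were lost. Without Sox4cKO CD44plus replicate 1 the antimicrobial (0.15), cholesterol (0.12), unfolded protein (0.11) and distal gut (-0.097) calls were lost. Without Sox4cKO CD44plus replicate 2 the class II (0.30) and unfolded protein (0.28) calls were lost.

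Outside the lists, Afp, the fetal serum protein alpha-fetoprotein, was at 39.4 and 28.1 CPM in control CD44plus and 3.18 and 6.63 CPM in Sox4cKO CD44plus (-2.77, SE 0.73, edgeR unadjusted p = 0.0014). Pnp2, a purine nucleoside phosphorylase gene beside its near-identical copy Pnp and therefore uncertain, was higher in Sox4cKO in both gates. It was at 1.52 and 0.731 CPM in control and 11.6 and 9.19 CPM in Sox4cKO in CD44plus (3.13, SE 0.84), and at 2.02 and 4.72 CPM against 14.4 and 52 CPM in CD44minus (3.25, SE 0.86). Neither gene passed edgeR's test over all genes with all 8 libraries.

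In the villus-enriched CD44minus gate 0 genes passed edgeR's test between genotypes, and the levels given here are without a call. They carry TMM factors of 0.527 in Sox4cKO replicate 2 and 1.09 to 1.72 in the other libraries of the gate. This raises the values of Sox4cKO replicate 2 against the others. After subtraction of background the factors of all libraries lay between 0.881 and 1.19. The sizes of the differences below therefore depend on the scaling. Nos2, the inducible nitric oxide synthase, was at 40.4 and 131 CPM in control and 221 and 796 CPM in Sox4cKO (2.56, SE 0.87), Duox2 at 62 and 167 against 234 and 658 CPM and Duoxa2 at 6.74 and 23.2 against 23.8 and 70.8 CPM. The metal-binding Mt1 was at 45.1 and 95.5 against 133 and 944 CPM, the cholesterol synthesis genes Sqle at 18.2 and 33.4 against 27.7 and 99.7 CPM and Fdps at 9.43 and 10.6 against 11.9 and 36.2 CPM. Cck was at 10.8 and 23.2 CPM in control and 14.4 and 3.81 CPM in Sox4cKO, and neurotensin (Nts) at 5.39 and 11.4 CPM in control, 0.99 CPM in Sox4cKO replicate 1 and 0 reads in replicate 2, which allows up to 0.431 CPM of gene counts. The ribosomal protein gene Rpl5 was at 2.69 and 1.18 against 4.46 and 13.3 CPM, uncertain because of its processed pseudogenes.

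edgeR called 0 genes in CD44minus, with 116 at an unadjusted p under 0.05 (109 higher, 7 lower), and DESeq2 and limma-voom with the animal as a random block called 0. The 116 are fewer than the share of 0.05 of the 20427 genes tested that is expected without any effect. Without Sox4cKO CD44minus replicate 1, the library with the most background, edgeR called 7613 genes (5558 higher, 2055 lower).

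limma's camera called the antimicrobial list (12 of 12 genes positive, median 1.35, limma's camera adjusted p = 2.89e-07), the cholesterol synthesis list (18 of 18, 1.04, limma's camera adjusted p = 2.89e-07) and the interferon response list (22 of 23, 0.79, limma's camera adjusted p = 3.37e-05) higher in Sox4cKO CD44minus (each adjusted p = 0.595 with an estimated correlation). Enterocyte genes (35 of 35 positive, 0.79, limma's camera adjusted p = 0.00123), oxidative phosphorylation genes (32 of 32, 0.89, limma's camera adjusted p = 0.00012) and ribosomal protein genes (77 of 83, 0.99, limma's camera adjusted p = 1.94e-07) were called higher (each adjusted p = 0.595 with an estimated correlation). Goblet cell genes (20 of 20, 0.61, limma's camera adjusted p = 0.00614), unfolded protein response genes (18 of 18, 0.90, limma's camera adjusted p = 0.000184), distal gut genes (8 of 10, 1.12, limma's camera adjusted p = 0.0165) and histone genes (46 of 59, 0.68, limma's camera adjusted p = 0.000699) were called higher (each adjusted p = 0.595 with an estimated correlation). Enteroendocrine genes (23 of 33 negative, -0.30, limma's camera adjusted p = 0.00411) and tuft cell genes (19 of 27 negative, -0.38, limma's camera adjusted p = 0.0138) were called lower (each adjusted p = 0.595 with an estimated correlation). With these moved dissociation stress genes (16 of 18 positive, 0.99, limma's camera adjusted p = 0.00467) and T cell genes (12 of 18 positive, 0.82, limma's camera adjusted p = 0.0165), called higher (each adjusted p = 0.595 with an estimated correlation). Stroma and endothelium genes (13 of 18 negative, -0.41, limma's camera adjusted p = 0.00884) and B, plasma and myeloid cell genes (10 of 16 negative, -0.12, limma's camera adjusted p = 0.0165) were called lower (each adjusted p = 0.595 with an estimated correlation). These are all 16 lists that camera called, and 0 were called by fry.

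The list calls in CD44minus depend on Sox4cKO replicate 2, the library with the least background of this gate. Without it the antimicrobial (0.20, adjusted p = 0.0775), cholesterol (-0.053), interferon (0.019), enteroendocrine (0.041), tuft (0.17), T cell (-0.16), B, plasma and myeloid (0.31) and distal gut (-0.13) calls were lost. Called by camera in the other direction were then oxidative phosphorylation (-0.94, adjusted p = 2.08e-19), enterocyte (-0.87, adjusted p = 2.08e-14) and ribosomal protein genes (-0.64, adjusted p = 1.79e-07). The same held for dissociation stress (-0.79, adjusted p = 3.22e-07), goblet (-0.56), unfolded protein (-0.51), stroma (0.40) and histone genes (-0.58). Without control CD44minus replicate 1 the enterocyte (0.40), oxidative phosphorylation (0.54), tuft (0.072), goblet (0.16), B, plasma and myeloid (0.17), stroma (-0.055), dissociation stress (0.62), unfolded protein (0.57), distal gut (0.91) and histone (0.40) calls were lost, and without control CD44minus replicate 2 the T cell call (0.97, adjusted p = 0.0539).

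The sizes in CD44minus also moved with the scaling. The median log2 fold change of all genes was 0.19 with TMM, -0.13 with upper quartile factors, -0.12 with total-count scaling and -0.0068 after subtraction of background. With these last 3 in turn, antimicrobial genes were at 0.76, 0.69 and 1.00, cholesterol at 0.45, 0.35 and 0.52, interferon at 0.24, 0.22 and 0.28, ribosomal protein at 0.34, 0.21 and 0.31, enteroendocrine at -0.55, -0.51 and -0.56 and distal gut genes at 0.55, 0.45 and 0.68, all still called. The tuft list was at -0.64, -0.54 and -0.64, without a call with total-count scaling (adjusted p = 0.054), and the unfolded protein list at 0.23, 0.10 and 0.097 and the histone list at 0.16, 0.029 and 0.13, without a call after subtraction. Without a call under both total-count scaling and subtraction were enterocyte (0.094, -0.055 and -0.11), oxidative phosphorylation (0.19, 0.034 and 0.024, adjusted p = 0.054 and 0.738), dissociation stress (0.29, 0.12 and 0.16), stroma (-0.47, -0.32 and -0.29) and B, plasma and myeloid cell genes (-0.36, -0.26 and -0.48). T cell genes were at 0.19, 0.086 and 0.19, without a call after subtraction, and goblet cell genes at 0.012, -0.079 and -0.063, without a call in any of the 3.

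Between the gates of control animals, crypt and villus genes separated. Olfm4 was at 14.8 and 33.8 CPM in CD44minus and 4340 and 4882 CPM in CD44plus (log2 fold change 7.56, SE 1.65, edgeR adjusted p = 0.0254). Cd44, the surface antigen used for the sort, was at 23.6 and 16.1 against 246 and 270.1 CPM (3.71, SE 0.87, edgeR adjusted p = 0.0332). The stem cell genes Smoc2 (3.86, SE 0.76, edgeR adjusted p = 0.0182), Lgr5 (2.87, SE 0.69, edgeR adjusted p = 0.0379) and Igfbp4 (3.72, SE 0.62, edgeR adjusted p = 0.014) rose in CD44plus. So did the replication licensing gene Mcm4 (4.58, SE 0.75, edgeR adjusted p = 0.014), the mitotic genes Ccna2 (4.02) and Ube2c (3.87) and the Wnt target Myc (3.28). Lct, the lactase of villus enterocytes, was at 814 and 1530 CPM in CD44minus and 58.5 and 36.5 CPM in CD44plus (-4.62, SE 1.20, edgeR adjusted p = 0.0494). The trehalase gene Treh (-4.27), the peptide transporter gene Slc15a1 (-4.25), the apolipoprotein gene Apoc3 (-3.35), the cobalamin receptor gene Cubn (-4.82) and the sphingomyelinase gene Enpp7 (-4.67) fell in CD44plus too.

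Of the lists, 11 of 22 stem cell genes passed over all genes, all higher in CD44plus, and adjusted over the list alone 20 were higher and 1 (Fstl1) lower (median 3.13, limma's camera adjusted p = 4.66e-18, adjusted p = 0.0217 with an estimated correlation). Of 33 cell cycle genes 22 passed and 32 over the list alone (median 2.98, limma's camera adjusted p = 2.87e-29, adjusted p = 0.0181 with an estimated correlation). Of 20 Wnt targets 4 and 11 did (median 1.97, limma's camera adjusted p = 5.51e-05, adjusted p = 0.0776 with an estimated correlation). Histone genes, which share reads and are uncertain singly, had 32 of 59 higher (median 3.86, limma's camera adjusted p = 2.42e-34, adjusted p = 0.166 with an estimated correlation), with Hist1h2an at 7.63 and Hist1h2ae at 5.46. Enterocyte genes were lower in CD44plus, 9 of 35 over all genes and 25 over the list alone (median -2.96, limma's camera adjusted p = 5.87e-21, adjusted p = 0.312 with an estimated correlation). Enteroendocrine genes were higher, 10 of 33 and 15 over the list alone, where 1 was lower (median 1.76, limma's camera adjusted p = 8.08e-11, adjusted p = 0.257 with an estimated correlation). Among them were Gip (8.66, SE 1.52, edgeR adjusted p = 0.014), Sst (4.55), Cpe (3.98) and Sct (3.35). T cell genes were higher, 6 of 18 and 14 over the list alone (median 3.22, limma's camera adjusted p = 8.41e-11, adjusted p = 0.292 with an estimated correlation), with Cd69 at 5.09 and Cd3e at 3.47. The mast cell proteases Mcpt1 (9.08) and Mcpt2 (6.29) rose.

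Antimicrobial genes of Paneth cells, which sit at the crypt base, were not higher in CD44plus. Of 18 Paneth cell genes 0 passed over all genes and 10 were lower when adjusted over the list alone (median -1.99, limma's camera adjusted p = 6.24e-06, adjusted p = 0.578 with an estimated correlation). The defensin gene Defa22 was at -2.66 (edgeR adjusted p = 0.0591, 0.00776 with the animal as a block). Mptx2 was at -2.79 (edgeR adjusted p = 0.116, 0.0478 with the block) and Ang4 at -2.61 (edgeR adjusted p = 0.119). Secretory progenitor and Notch genes were higher in part, 3 of 21 over all genes (median 1.12, limma's camera adjusted p = 0.00082, adjusted p = 0.257 with an estimated correlation). Among them were the receptor gene Notch1 (3.07) and the Notch glycosyltransferase gene Lfng (2.75). The goblet cell transcription factor gene Spdef did not pass (1.67, SE 0.60, edgeR adjusted p = 0.132). The goblet cell list (median 0.85, limma's camera adjusted p = 0.0042, adjusted p = 0.614 with an estimated correlation) lost its call without control CD44minus replicate 1 (median 0.40). Interferon response genes were lower (median -1.30, limma's camera adjusted p = 0.00314, adjusted p = 0.594 with an estimated correlation), with Ifit1 at -2.87. That call was lost without control CD44minus replicate 2 (median -0.67). The acute phase gene Saa1 (-5.44) fell. Kctd12 (2.59) rose, but the tuft list it belongs to was not called (median 0.40, limma's camera adjusted p = 0.165, -0.47 with upper quartile factors). The mesenchymal filament gene Vim (4.66) rose against its list, as stroma and endothelium genes were lower (16 of 18 negative, median -2.19, limma's camera adjusted p = 0.00623, adjusted p = 0.614 with an estimated correlation). The stroma call was lost with upper quartile factors (adjusted p = 0.0946), total-count scaling and subtraction. Dissociation stress genes were higher (16 of 18 positive, median 1.00, limma's camera adjusted p = 0.0125, adjusted p = 0.614 with an estimated correlation), without a call after subtraction (0.69) or without control CD44minus replicate 1 (0.65). Ribosomal protein genes, uncertain for shared reads, had 11 of 83 higher and 62 over the list alone (median 2.52, limma's camera adjusted p = 1.88e-23, adjusted p = 0.312 with an estimated correlation), with Rpl5 at 3.78.

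In the test across control gates edgeR called 502 genes, 411 higher and 91 lower in CD44plus, and 4694 at an unadjusted p under 0.05. With the animal as a block the count was 3659 (1506 higher, 2153 lower), which held all 502. With the 4 control libraries alone it was 9877 (4397 higher, 5480 lower), which also held all 502. The Sox4cKO libraries are not in this comparison and enter it only through the filter, scaling and spread of the shared fit. The count of 502, and genes given here as not passing, therefore depend on those libraries too. DESeq2 called 2224 (1144 higher, 1080 lower), among them 501 of the 502, and limma-voom with the animal as a random block 2176 (946 higher, 1230 lower). In the simulation of this fit 14 of DESeq2's 30 calls were false. Few genes were changed there, so that share does not carry over to the 2224. The split moved with the scaling, to 384 higher and 176 lower with DESeq2 size factors, 380 and 504 with upper quartile factors and 1416 and 675 with total-count scaling, and to 1612 and 525 after subtraction of background. The median of all genes was -0.19 with TMM and -0.52, -1.01, -0.77 and 0.20 under these 4 in turn. The count was 34 without control CD44minus replicate 1, 0 without control CD44minus replicate 2, and 24 and 6 without control CD44plus replicate 1 and replicate 2. It was 7362 and 7138 without Sox4cKO CD44minus replicate 1 and replicate 2, and 332 without Sox4cKO CD44plus replicate 2. Without control CD44minus replicate 2, the 0 calls of edgeR came with 2664 genes at an unadjusted p under 0.05, and the other tools were not run without a library.

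**Figure D4:**
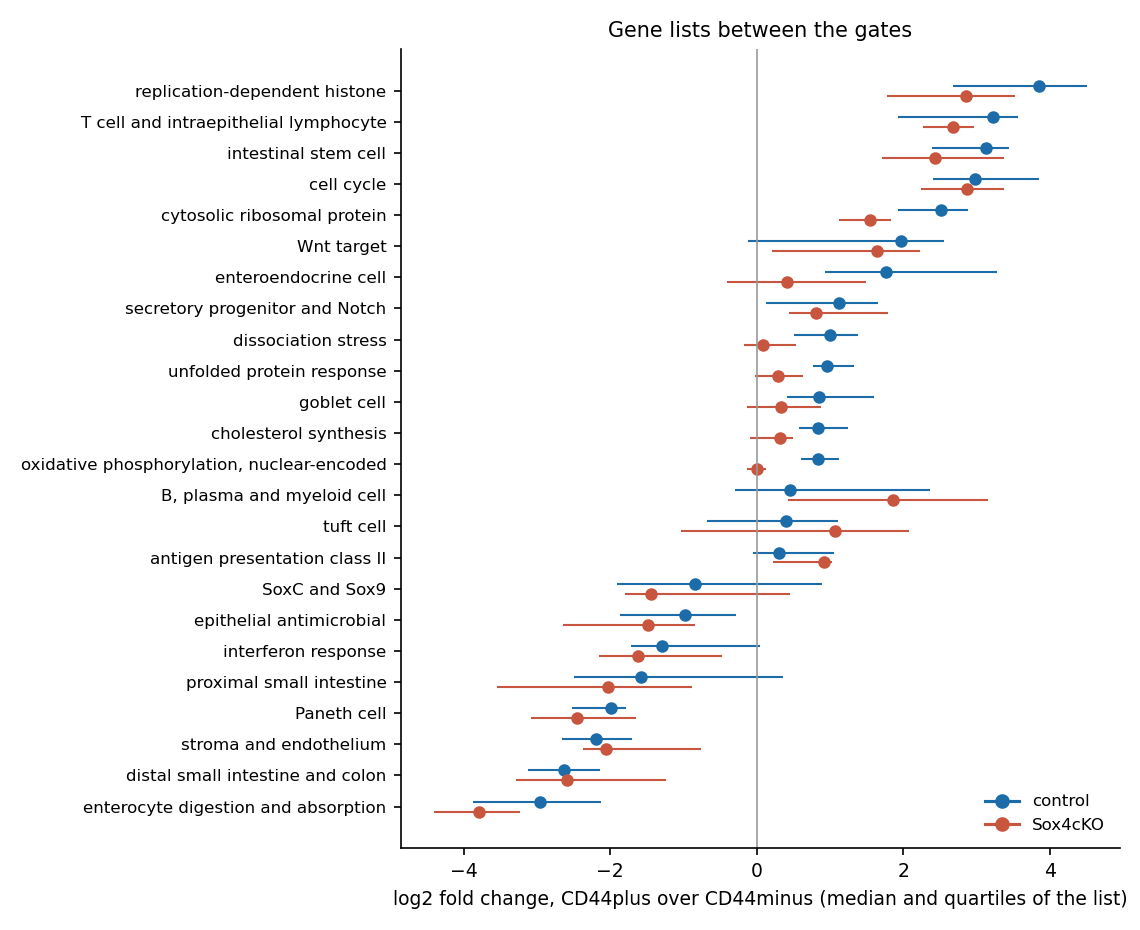
Median log2 fold change of CD44plus against CD44minus for the gene lists, 1 point for control and 1 for Sox4cKO, with lines from the first to the third quartile of the list. Stem cell genes lay at 3.13 in control and 2.44 in Sox4cKO, enterocyte genes at -2.96 and -3.80, and enteroendocrine genes at 1.76 and 0.41, the last turning sign in Sox4cKO with upper quartile factors and total-count scaling.

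Between the gates of Sox4cKO animals the same crypt and villus groups separated. Olfm4 (6.32, SE 1.56, edgeR adjusted p = 0.0383), Cd44 (4.03, SE 0.88, edgeR adjusted p = 0.023), Smoc2 (3.26), Igfbp4 (3.78), Mcm5 (3.60), Ube2c (3.60) and Myc (3.92) rose in CD44plus. Lct (-4.85, SE 1.21, edgeR adjusted p = 0.0408), Treh (-4.46), Slc15a1 (-4.59), Apoc3 (-4.39), the neutral amino acid transporter gene Slc6a19 (-4.20) and the ileal bile acid transporter gene Slc10a2 (-4.84) fell. Lgr5 did not pass over all genes (2.21, SE 0.68, edgeR adjusted p = 0.0961) but passed adjusted over the list alone (0.0154) and with the animal as a block (edgeR adjusted p = 0.0168). Of 22 stem cell genes 8 passed and 17 over the list alone (median 2.44, limma's camera adjusted p = 3.86e-20, adjusted p = 0.00879 with an estimated correlation). Of 33 cell cycle genes 19 and 31 did (median 2.87, limma's camera adjusted p = 2.58e-37, adjusted p = 0.00879 with an estimated correlation), and of 20 Wnt targets 3 and 8, with 1 lower over the list alone (median 1.64, limma's camera adjusted p = 8.58e-07, adjusted p = 0.0406 with an estimated correlation). Enterocyte genes were lower, 17 of 35 and 30 over the list alone (median -3.80, limma's camera adjusted p = 2.29e-29, adjusted p = 0.25 with an estimated correlation). Paneth cell genes were lower too, 3 of 18 and 12 over the list alone (median -2.46, limma's camera adjusted p = 3.49e-08, adjusted p = 0.338 with an estimated correlation), among them Defa5 (-3.92), Defa22 (-3.49) and Mptx2 (-3.81).

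Immune and mast cell genes rose too in Sox4cKO CD44plus against CD44minus. Mcpt1 (10.74, SE 1.93, edgeR adjusted p = 0.0139), Mcpt2 (8.81), Cma2 (6.63), Cpa3 (6.09), the immunoglobulin joining chain gene Igj (6.57), Itgax (4.58) and Alox5ap (5.14) rose. So did Cd69 (4.45), Vim (4.31) and Hist1h2an (5.63), while Nos2 (-3.63) fell. The stroma and endothelium list, which holds Vim, was not called (16 of 18 negative, median -2.06, limma's camera adjusted p = 0.147). T cell genes (median 2.68, limma's camera adjusted p = 6.15e-16, adjusted p = 0.225 with an estimated correlation) and B, plasma and myeloid cell genes (median 1.86, limma's camera adjusted p = 5.23e-08, adjusted p = 0.338 with an estimated correlation) were called higher. Tuft cell genes (median 1.06, limma's camera adjusted p = 0.000112, adjusted p = 0.338 with an estimated correlation) and Notch genes (median 0.81, limma's camera adjusted p = 0.000112, adjusted p = 0.199 with an estimated correlation) were higher as well, and so were histone genes (median 2.85, limma's camera adjusted p = 4.07e-36, adjusted p = 0.104 with an estimated correlation) and ribosomal protein genes (median 1.54, limma's camera adjusted p = 8.83e-19, adjusted p = 0.338 with an estimated correlation). Interferon response genes (median -1.62, limma's camera adjusted p = 1.20e-05, adjusted p = 0.338 with an estimated correlation) and epithelial antimicrobial genes (median -1.49, limma's camera adjusted p = 0.00272, adjusted p = 0.352 with an estimated correlation) were called lower. Enteroendocrine genes were higher by a small median, 2 of 33 over all genes and 4 over the list alone (median 0.41, limma's camera adjusted p = 0.000532, adjusted p = 0.338 with an estimated correlation). Gip (6.34, SE 1.41, edgeR adjusted p = 0.0234) and Sst (4.09) were among them. Chgb did not reach the threshold (3.83, SE 1.12, edgeR adjusted p = 0.0799), and Cpe lay at 0.86 (edgeR adjusted p = 0.444). Their median was -0.21 with upper quartile factors and -0.10 with total-count scaling. Without Sox4cKO CD44minus replicate 2 the enteroendocrine (0.088), tuft (0.59), interferon (-1.05) and antimicrobial (-0.86) calls were lost.

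For Sox4cKO gates edgeR called 529 genes, 339 higher and 190 lower in CD44plus, and 3611 at an unadjusted p under 0.05. The count was 1712 (807 higher, 905 lower) with the animal as a block, which held all 529. It was 1781 (721 higher, 1060 lower) with DESeq2, which held 528 of the 529, and 1105 with limma-voom and the animal as a random block. In the simulation of this fit 16 of DESeq2's 32 calls were false. Few genes were changed there, so that share does not carry over to the 1781. The count was 0 with the 4 Sox4cKO libraries alone, where 2154 genes had an edgeR unadjusted p under 0.05 and the other tools were not run. The split was 329 higher and 312 lower with DESeq2 size factors, 409 and 576 with upper quartile factors and 1484 and 502 after subtraction of background. The median of all genes was -0.48 with TMM, -0.72 with DESeq2 size factors, -0.93 with upper quartile factors, -0.72 with total-count scaling and 0.27 after subtraction. Leaving out a library gave 298 genes without control CD44minus replicate 2, 226 and 243 without control CD44plus replicate 1 and replicate 2, 3379 and 8440 without Sox4cKO CD44minus replicate 1 and replicate 2. It gave 11 without Sox4cKO CD44plus replicate 2. Of the genes higher in CD44plus, 214 were called in both genotypes (6.82 expected for independent lists), and of those lower 85 (0.846 expected), and 0 were called in opposite directions by edgeR. Both lists come from the same fit with a shared spread per gene. They are thus not independent, and the expected values are no baseline for agreement between genotypes.

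The genotype effect was set against itself in the 2 gates through the difference of the log2 fold changes, CD44plus less CD44minus. Cpe had a difference of -3.12 (SE 0.90, edgeR unadjusted p = 0.00287) and Tac1 of -3.13 (SE 1.01, unadjusted p = 0.00613), with the lower value in CD44plus. In CD44minus the median level of enteroendocrine genes was only 10.8 and 7.47 CPM in control and 9.41 and 3.54 CPM in Sox4cKO. These differences thus rest on low values in libraries of unequal background on that side. Emilin2 (2.97, SE 0.94) and Igj (3.28, SE 1.37) lay on the other side, and Sox4 itself had a difference within its error (0.44, SE 0.98). edgeR called 0 genes, with 50 at an unadjusted p under 0.05 (19 higher, 31 lower), and DESeq2 and limma-voom with the animal as a random block called 0. The 50 are fewer than the share of 0.05 of the 20427 genes tested that is expected without any effect. Without Sox4cKO CD44minus replicate 1 edgeR called 254 (151 higher, 103 lower). By limma's camera 8 of 24 lists differed and 0 with an estimated correlation, among them the enteroendocrine list (median -1.45, camera adjusted p = 6.21e-12, adjusted p = 0.833 with an estimated correlation), which without Sox4cKO CD44minus replicate 1 had a median of -0.46 (adjusted p = 0.305).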

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

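The tests of depth and of a property of the gate were chosen after the background had been seen. Total-count scaling and subtraction of background were also chosen after seeing the data. The prediction for genomic DNA names the 2 libraries of most background, so the background was known when it was written. The other results here were planned. These 8 gene lists were singled out because their genotype effect differed between the 2 gates by limma's camera, as medians of the log2 difference, CD44plus less CD44minus. Enteroendocrine genes had a median of -1.45 (camera adjusted p = 6.21e-12) and tuft cell genes of 0.54 (3.53e-05), each adjusted p = 0.833 with an estimated correlation. B, plasma and myeloid cell genes had 0.92 (5.72e-08) and stroma and endothelium genes 0.24 (0.00997), each adjusted p = 0.833 with an estimated correlation. Cholesterol synthesis genes had -0.71 (0.0338), oxidative phosphorylation genes -0.85 (0.00227), ribosomal protein genes -1.04 (6.72e-07) and histone genes -0.87 (3.53e-05), each adjusted p = 0.833 with an estimated correlation. With the animal as a replicate block the cholesterol call was lost (-0.52, adjusted p = 0.0756), while stroma was at 0.65 and oxidative phosphorylation at -0.40 with their calls kept. Without control CD44minus replicate 2 the medians were 0.98 (tuft), 0.61 (stroma), -1.09 (cholesterol), -1.40 (oxidative phosphorylation), -1.62 (ribosomal protein) and -1.43 (histone). limma's fry gave an adjusted p of 0.944 for each. Without Sox4cKO CD44minus replicate 2 the medians were 0.042 (tuft), 0.39 (B, plasma and myeloid), -0.40 (stroma), 0.44 (cholesterol), 1.04 (oxidative phosphorylation), 0.60 (ribosomal protein) and 0.27 (histone), with cholesterol, oxidative phosphorylation and ribosomal protein genes called in the other direction and the rest without a call. Without control CD44minus replicate 1 they were -0.20 (stroma), -0.44 (cholesterol), -0.46 (oxidative phosphorylation), -0.65 (ribosomal protein) and -0.50 (histone), all without a call. Without Sox4cKO CD44plus replicate 1 the stroma (-0.70), cholesterol (-0.53), oxidative phosphorylation (-0.64), ribosomal protein (-0.66) and histone (-0.46) calls were lost. Without Sox4cKO CD44plus replicate 2 the tuft (0.32) and cholesterol (-0.60) calls were lost, without control CD44plus replicate 2 the cholesterol call (-0.68), and without Sox4cKO CD44minus replicate 1 the enteroendocrine call (-0.46, adjusted p = 0.305). The B, plasma and myeloid median was also 0.31 without Sox4cKO CD44plus replicate 2, 0.47 without control CD44plus replicate 1, 0.58 without control CD44minus replicate 1, 1.41 without Sox4cKO CD44plus replicate 1 and 1.67 without control CD44plus replicate 2, with its call kept. Without Sox4cKO CD44minus replicate 1 the medians were 1.43 (tuft), 2.36 (B, plasma and myeloid), 2.02 (stroma), -1.26 (cholesterol), -1.61 (oxidative phosphorylation), -1.70 (ribosomal protein) and -1.27 (histone), all still called. The tuft median was 0.22 without control CD44minus replicate 1, with its call kept.

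The sizes also moved with the scaling. The median difference of all genes was -0.37 with TMM, -0.0037 with upper quartile factors, -0.017 with total-count scaling and -0.0073 after subtraction of background. With these last 3 in turn, enteroendocrine genes were at -1.28, -1.40 and -1.13, tuft cell genes at 0.65, 0.55 and 1.06, B, plasma and myeloid cell genes at 1.15, 0.96 and 1.47, ribosomal protein genes at -0.40, -0.38 and -0.48 and histone genes at -0.34, -0.28 and -0.30, all still called by camera. Stroma and endothelium (0.33, 0.22 and 0.030) and cholesterol synthesis genes (-0.16, -0.087 and -0.17) had no call in any of the 3, and oxidative phosphorylation genes (-0.17, -0.046 and 0.045) only with upper quartile factors.

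Background reads were high in 3 of the 4 CD44minus libraries. Lower depth alone is argued against, because receptor genes took 12.5 times as large a share of the gene counts in control CD44minus replicate 1 as in control CD44plus replicate 1. A property of CD44minus cells stays open, since only 1 library of that gate, Sox4cKO CD44minus replicate 2 with 182 CPM of gene counts on these genes, lay under the highest CD44plus library. A candidate explanation is genomic DNA, for which silent genes on the single X chromosome of a male should have reads for 1 copy where autosomal ones have 2, and this ratio was 0.408 (bootstrap 95% interval 0.334 to 0.515) in Sox4cKO CD44minus replicate 1 and 0.397 (0.325 to 0.55) in control CD44minus replicate 1, under the lowest value predicted by less than its interval. It was also 0.361, 0.458 and 0.43 in control CD44minus replicate 2, control CD44plus replicate 1 and Sox4cKO CD44plus replicate 1, and transcription leaking from 1 X copy could give the same ratio, so the source stays open. Apart from a property of CD44minus cells, no biological explanation was tested.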

How the results depend on the processing

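Across the gene lists the text reports, 1214 recalculated medians kept direction and side of the threshold, 88 lost the call, 29 gained one and 83 turned the sign of the median or camera's direction, and for named genes these were 2425, 243, 229 and 13. The tally of lists holds camera with its preset correlation only, not the estimated correlation or fry, under which most calls were lost. Counts were within 1.5 times of the main count in 148 recalculations and outside in 87. A count of 0 that stayed at 0 is among the former. The cause of a change was not tested unless given. Spread limits the genotype comparisons, as edgeR recovered 0 of 100 simulated 2-fold changes in either gate with all 8 libraries, against 72 in CD44plus and 32 in CD44minus at the same depths and a coefficient of variation of 0.1. Set tests were not run with DESeq2 or limma-voom, and the fit of 4 libraries and DESeq2 do not cover every result.

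Genes called between genotypes in CD44plus were 17 with the 4 libraries, a fit with a lower spread, and 61 (23 higher, 38 lower) with sample quality weights, against 0 in the main analysis (128 at an edgeR unadjusted p under 0.05, 0 by DESeq2 and by limma-voom with the animal as a random block). Leaving out a library gave 58 to 1554 in the fit of 4 libraries. With all 8 libraries at the start it gave 0 to 24 in CD44plus, 0 to 7613 in CD44minus, 0 to 254 for the difference between gates, 0 to 7362 between control gates and 11 to 8440 between Sox4cKO gates. Between control gates the count of 502 was 1275 at a threshold of 0.1, 884 with upper quartile factors, 994 without a filter and 955 with a stricter one. It was 9877 (4397 higher, 5480 lower) with the 4 libraries, 1074 without the 20 highest genes, 2091 with total-count scaling and 2137 after subtraction of background. It was 2224 with DESeq2, 2176 with limma-voom and a random animal block and 10759 with quality weights. Between Sox4cKO gates the count of 529 was in the same order 1001, 985, 884, 1023, 0, 1019, 2039, 1986, 1781, 1105 and 95. Total-count scaling, subtraction and quality weights were chosen after seeing the data.

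The replicate block pairs animals between gates, where the count was 3659 in control and 1712 in Sox4cKO. Beyond the genes given with it and the cholesterol list in the difference between gates, the block changed no call of a list the text names for these comparisons. Of all 24 lists it called 19 between control gates, 20 between Sox4cKO gates and 7 for the difference, against 20, 17 and 8 without it. Between genotypes the replicates share only a number (deviations correlated at 0.6 in CD44minus and 0.275 in CD44plus), and the replicate block called 1 gene (Cpe, lower) in CD44plus and 0 in CD44minus. With the replicate block the SoxC and Sox9 list in CD44plus had an adjusted p of 0.0762, the B, plasma and myeloid list in CD44minus 0.0616, Neurog3 a log2 fold change of 0.023, and 22 enteroendocrine genes passed over the list alone.

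Of the 24 lists, 16 were called in CD44minus, 12 in CD44plus, 20 between control gates, 17 between Sox4cKO gates and 8 for the difference. With an estimated correlation these were 0, 0, 2, 3 and 0, and with fry 0, 1, 6, 5 and 0. Subtraction left 8 in CD44minus. Leaving out a library gave 7 to 18 in CD44minus, 5 to 17 in CD44plus and 4 to 15 for the difference. The count of 8 enteroendocrine genes was 4 with upper quartile factors, 14 without a filter, 4 with a stricter one, 28 with the 4 libraries, 13 without the 20 highest genes and 1 after subtraction. It was 14 with limma-voom and a random animal block, 28 with quality weights and 0 to 30 without a library.

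Medians that turned sign under a setting were, in CD44plus, the Notch list with total-count scaling (-0.029) and the cell cycle list with upper quartile factors (-0.061), without the 20 highest genes (-0.014), with total-count scaling (-0.099) and after subtraction (-0.033). Oxidative phosphorylation turned with upper quartile factors (-0.041), total-count scaling (-0.089) and subtraction (-0.0069). In CD44minus the enterocyte list turned with total-count scaling (-0.055) and subtraction (-0.11), as did the goblet list (-0.079 and -0.063), while for stroma (-0.29) subtraction turned camera's direction without a call. Between control gates the tuft median was -0.47 with upper quartile factors and -0.30 with total-count scaling. In the difference, subtraction turned oxidative phosphorylation to 0.045, and for stroma it turned camera's direction without a call, the median staying positive at 0.030. Between Sox4cKO gates the enteroendocrine median was -0.21 with upper quartile factors and -0.10 with total-count scaling. Tph1 in CD44plus was -0.27 with limma-voom and a random animal block and -0.035 with quality weights.

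List calls also lost under a setting were, after subtraction, goblet between control gates (0.61, adjusted p = 0.204) and enteroendocrine between Sox4cKO gates (1.22, adjusted p = 0.081). The latter was lost with the 4 libraries too (0.21, adjusted p = 0.0522), and tuft between Sox4cKO gates with total-count scaling (0.40, adjusted p = 0.0653). In CD44minus the B, plasma and myeloid call was lost with the 4 libraries (-0.21, adjusted p = 0.391). In the difference, cholesterol lost its call with upper quartile factors (-0.16), a stricter filter (-0.32), removal of the 20 highest genes (-0.39), total-count scaling (-0.087) and subtraction (-0.17). There stroma lost its call with upper quartile factors (0.33) and total-count scaling (0.22), and oxidative phosphorylation with total-count scaling (-0.046).

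Ranges over left-out libraries that cross 0 were, in CD44plus, -0.0098 to 0.34 for tuft, -0.15 to 0.088 for goblet, -0.010 to 0.14 for Notch, -0.066 to 0.098 for cell cycle, -0.26 to 0.35 for enterocyte and -0.21 to 1.06 for T cell genes. They were also -1.39 to 0.37 for stroma, -0.18 to 0.37 for dissociation stress, -0.12 to 0.054 for oxidative phosphorylation and -0.52 to 0.11 for proximal gut, and -0.097 to 1.08 for distal gut, -0.20 to 0.076 for ribosomal protein and -0.34 to 0.083 for histone genes. In CD44minus they were -0.053 to 1.67 for cholesterol, -1.68 to 0.041 for enteroendocrine, -1.19 to 0.17 for tuft, -0.87 to 1.49 for enterocyte, -0.94 to 1.67 for oxidative phosphorylation and -0.64 to 1.68 for ribosomal protein genes. There they were also -0.56 to 1.33 for goblet, -0.16 to 1.26 for T cell, -1.65 to 0.31 for B, plasma and myeloid, -2.35 to 0.40 for stroma, -0.79 to 1.70 for dissociation stress, -0.51 to 1.59 for unfolded protein, -0.13 to 1.38 for distal gut and -0.58 to 1.32 for histone genes. Between Sox4cKO gates stroma ranged -3.11 to 0.68. In the difference they were -0.70 to 2.02 for stroma, -1.26 to 0.44 for cholesterol, -1.61 to 1.04 for oxidative phosphorylation, -1.70 to 0.60 for ribosomal protein and -1.43 to 0.27 for histone genes. Single genes in CD44plus, with leaving out a library in the 4-library fit included, ranged -0.29 to 0.12 (Neurog3), -1.07 to 0.88 (Tph1), -0.81 to 0.045 (Pou2f3), -0.0064 to 0.29 (Trpm5) and -0.059 to 1.69 (Cd69). The difference for Sox4 ranged -0.57 to 2.21.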

Other observations

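The tests of dilution and of a more distal stretch of gut, the test of a type 2 response, and the set of genes in the next paragraph were chosen after the results had been seen.

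In the fit of the 4 CD44plus libraries, 5 of the 17 genes lower in Sox4cKO were neither Sox4 nor in the enteroendocrine list. Map1b, a microtubule-associated protein of neurons, was at 87.5 and 93.5 CPM in control and 23.1 and 17.8 CPM in Sox4cKO. Pclo, a scaffold protein of the presynaptic zone, was at 106 and 142 against 39.8 and 34.3 CPM, and Ptprn2, a membrane protein of secretory granules, at 173 and 208 against 62.5 and 65.8 CPM. The T-type calcium channel gene Cacna1h was at 34.3 and 27.6 against 6.36 and 5.4 CPM and Sphkap, which anchors protein kinase A, at 32.3 and 40.7 against 7.23 and 7.86 CPM. Their log2 fold changes with all 8 libraries were -2.14, -1.74, -1.57, -2.39 and -2.27, and none of the 5 passed edgeR's test there.

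Enteroendocrine genes were lower in Sox4cKO CD44plus. Dilution by leukocyte or mast cell RNA in Sox4cKO CD44plus replicate 2 is argued against as the whole cause, since the list median was -1.74 without that library, and background reads in the control libraries likewise, since it was -1.78 after subtraction. A more distal stretch of gut in the knockout animals is argued against as the whole cause by the distal hormones Gcg, Pyy and Nts, whose summed level in Sox4cKO was 0.408 of that in control (82.2 and 74.3 CPM in control, 28.9 and 35 CPM in Sox4cKO), a sum that is mostly Gcg. It stays open in part, because Nts, near the floor, went the other way (0.357 and 0.183 against 1.16 and 0.474 CPM). The distal gut list was also higher in Sox4cKO, by a median of 0.53 that was -0.097 without Sox4cKO CD44plus replicate 1. With the 4 CD44plus libraries its 6 genes tested were all positive (median 0.81, limma's camera adjusted p = 6.57e-07, adjusted p = 0.31 with an estimated correlation). Proximal gut genes had a median of -0.35 without a call (6 of 9 negative), and Pdx1 was lower in both Sox4cKO libraries than in both control libraries. That Sox4 deletion lowers the number or the hormone content of enteroendocrine cells is a hypothesis that may account for the pattern, with 2 animals per genotype, no estimated-correlation call and other differences between animals untested, and counts of hormone-positive cells, not in these data, would tell number from content.

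Of 7 mast cell proteases, 4 were highest in Sox4cKO CD44plus replicate 2. Reads shared between the close paralogs of the cluster are argued against as the whole cause, since 6 single-copy mast cell genes (Cpa3, Kit, Fcer1a, Ms4a2, Hdc and Gata2) had a median of 3.91 times the highest other CD44plus library. A type 2 response of the epithelium stays open, since Retnlb (0.386 of the highest other CD44plus library) and Il25 (0 reads there) were near the floor in every CD44plus library. RNA of mast cells sorted with the epithelium may explain the pattern, with Cpa3 at 4.34 times the highest other CD44plus library. Of 8 other mast cell genes 6 were highest in Sox4cKO CD44plus replicate 2 of all 8 libraries (not Hdc or Cd200r3), and 0 of the 15 mast cell genes are in another list. Hdc and Cd200r3 were higher in CD44minus libraries of high background. In Sox4cKO CD44plus replicate 2 they were at 1.75 and 0.98 times the highest other CD44plus library. The CD326 gate should remove mast cells, but T cell genes had a median level of 76.3 and 140.1 CPM in control CD44plus. The gate thus did not keep out all immune cell RNA and does not settle the question. With 1 of 2 animals an effect of the knockout stays untested.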
